A study of Arabidopsis thaliana with 24 samples.

How the data were processed

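Expression was measured in 24 samples on ATH1 arrays, 12 of roots and 12 of shoots, in 12 groups of 2. The deposited values are intensity signals per probe set on a linear scale, and the submitters' processing notes name MAS5; its version is not given in the sources used here. The trimmed mean was nearly the same on every array, as 1 scaling factor per array would give. The table held 22810 probe sets, and 64 control probe sets were left out of the tests. Signals were put on the scale log2(signal + 2.205), the pseudocount being the 10th percentile of all values, and the deposited scaling was kept. A probe set was kept when at least 2 of the 24 arrays lay at or above the median of all values, 41.7, which left 15199.

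All arrays entered 1 fit with a mean for each of the 12 groups, by lmFit and eBayes with a trend in limma 3.58.1 under R 4.3.3. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The fit had 12 residual degrees of freedom, and the prior added 4.15. Each time was compared with 0.5 h in the same tissue, the interaction compared these changes between roots and shoots, and 1 contrast compared the tissues over all times. Tests were two-sided moderated tests, adjusted by Benjamini-Hochberg over the probe sets kept within a contrast, and a call needed an adjusted p under 0.05 and a difference of at least 2-fold. Replicate numbers were not used as a block, since the labels do not say what they share, and groups of 2 were not tested for outlying arrays.

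Of all probe sets, 13513 mapped to 1 gene, 503 to several and 8794 to none in the gene table used; 13436 were matched through gene identifiers. Of those kept, 1180 carried a symbol other than a locus code and 6944 a locus code. The rule for named genes took, per tissue, the 8 highest and 8 lowest differences at 24 h and the 4 highest and 4 lowest at 3 h among called probe sets of 1 named gene for which both arrays of one time lay above both of the other, and the 4 highest and 4 lowest of the interaction at each of these times. It also took up to 4 members per gene list by the F test over time all members of the abscisic acid, clock and reference lists, and a few genes fixed by name. The rule was fixed before the data were examined; the 4 highest and 4 lowest among locus codes were added after the gene table was seen.

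Before the data were examined, 30 gene lists were fixed, and lists with at least 5 measured members were tested, which left auxin, heat shock and photosynthesis. Another 24 lists were written after the gene names and before any difference was computed, of which 23 were tested as a family of their own. These were LEA and dehydrin, stress-inducible, chaperone, endoplasmic reticulum stress, autophagy, UDP-glycosyltransferase, glutathione transferase, CYP71B, wall loosening, beta-glucosidase, endoplasmic reticulum body, SWEET, tubulin, tetraspanin, vacuolar, further photosynthesis, further jasmonate, calmodulin-like and glutamate receptor, histone, cell division, ribosomal protein, plastid-encoded and mitochondrially encoded genes. Lists were tested by limma's camera with a preset correlation of 0.01, with 1 probe set per gene, and adjusted within a set of lists and a tissue or the interaction, 15 tests for the fixed and 115 for the added lists. With an estimated correlation, 4 tests passed in roots and 4 in shoots, all of the stress-inducible list.

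Alternatives were other pseudocounts, scalings and filters, no trend, a replicate block, each tissue alone, other limits for a call, 1 h as the reference, each array left out in turn, and for lists an estimated correlation, fry, the mean of probe sets and quantile normalization. Fits without the root arrays of 12 h were added after the data were seen. The procedure was tested on simulated data with 200 changed probe sets in roots at 24 h: 83 of 100 with a log2 size of 1.5 and 100 of 100 with a log2 size of 3 were called, with 2 false calls. The simulated noise was independent between probe sets and arrays, with the same spread of a probe set in all groups. False calls where groups differ in spread, as roots at 12 h did, were therefore not tested. Nor were those where 1 array shifts many probe sets together.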

Results

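Transcript levels were measured in shoots and roots of Arabidopsis thaliana Col-0, the standard laboratory accession, after sodium chloride was added to the growth medium to 150 mM on day 16. Samples were taken 0.5, 1, 3, 6, 12 and 24 h later, and each of the 12 tissue and time groups holds 2 arrays, 24 in all. The arrays carry short oligonucleotide probe sets, and the values are signals on a linear scale. The median signal per array lay between 37.2 and 42.0 in shoots and between 41.9 and 47.2 in roots. Every array had been scaled to nearly the same trimmed mean. Untreated plants were not analysed here, so each time was compared with 0.5 h in the same tissue, and time after salt runs together with time of day. Salt was added after 3 h of light in days of 16 h of light, which puts 24 h and 0.5 h at nearly the same time of day, while 3, 6 and 12 h fell later in the day. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Signals are given below as mean ± SD of 2 arrays (n = 2) and differences as log2 ± SE from limma, on the scale log2(signal + 2.205), which understates the change of dim genes.

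The 2 arrays of 11 groups correlated across 15199 probe sets with Pearson r from 0.961 to 0.984. The 2 root arrays of 12 h correlated at 0.857, and 2902 probe sets (19.1%) differed at least 2-fold between them, against 883 at most in another group. Replicate 1 of that group correlated best with a root array of 6 h (r = 0.954) and replicate 2 with a root array of 24 h (r = 0.930). These correlations are across probe sets, which are not independent replicates. Results for roots at 12 h are therefore given with the values without each of these arrays.

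**Figure D1:**
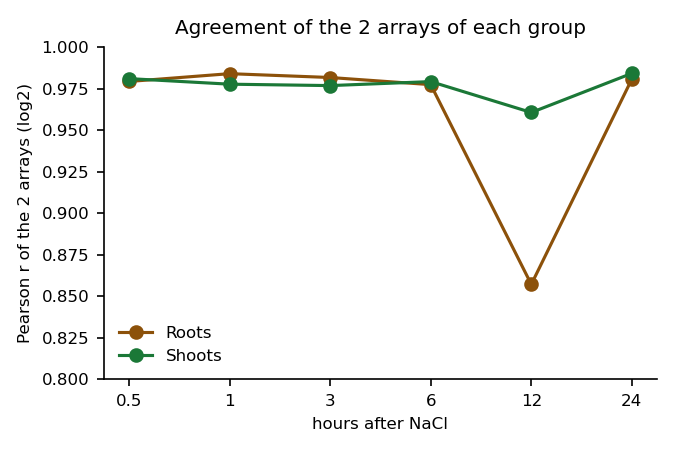
Pearson correlation across probe sets of the log2 values of the 2 arrays of each group (vertical axis, from 0.8 to 1) by hours after NaCl (horizontal axis, times spaced evenly), with 1 point per group and a line per tissue. Roots at 12 h lie at 0.857, below the other 11 groups.

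Roots and shoots were compared first through genes known to mark each tissue. All 9 measured nuclear photosynthesis genes were lower in roots than in shoots, with PRK (AT1G32060), phosphoribulokinase of the Calvin cycle, at a mean signal of 28.1 ± 13.0 over 12 root arrays and 3845 ± 745 over 12 shoot arrays. PYK10 (AT3G09260), a beta-glucosidase of endoplasmic reticulum bodies that is abundant in roots, had signals of 3484 ± 429.7 in roots and 474 ± 227 in shoots (n = 12 each). FMA (AT3G24140), a regulator of stomatal guard cells, differed by -2.26 ± 0.14 (adjusted p = 6.78e-11), and EXPA7 (AT1G12560), a root hair expansin, by 1.43 ± 0.23 (adjusted p = 1.86e-05). Averaged over the 6 times, 3404 probe sets were higher and 2801 lower in roots than in shoots.

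The comparison of 24 h with 0.5 h asks which transcripts had moved after a day of salt at nearly matched clock time. The plants were also older at 24 h, which cannot be told from an effect of salt without untreated plants. In roots, stress-inducible genes rose as a group (adjusted p = 0.0106 with an estimated correlation), NDB4 and ATHSP22.0 were among the largest rises, and BCAT4 fell furthest among genes with a symbol. NDB4 (AT2G20800), an alternative NAD(P)H dehydrogenase of mitochondria, went from a signal of 1.68 ± 0.598 to 208 ± 66.6 (5.73 ± 0.71, adjusted p = 4.20e-05). ATHSP22.0 (AT4G10250), a small heat shock protein of the endoplasmic reticulum, went from 12.1 ± 4.81 to 621 ± 94.4 (5.48 ± 0.58, adjusted p = 1.08e-05). LEA4-5 (AT5G06760), a late embryogenesis abundant (LEA) protein of drying tissue, rose by 3.93 ± 0.58 to a signal of 939 ± 288. COR27 (AT5G42900), a cold-regulated gene, rose by 4.43 ± 0.47, and the beta-glucosidases BGLU24 (AT5G28510) and BGLU27 (AT3G60120) rose by 4.48 ± 0.51 and 4.36 ± 0.57. JRG21 (AT3G55970), a jasmonate-regulated gene, rose by 4.12 ± 0.54 and CML37 (AT5G42380), a calmodulin-like protein, by 3.82 ± 0.68. BCAT4 (AT3G19710), which starts the chain elongation of methionine for glucosinolates, fell from 915 ± 56.3 to 61.3 ± 29.5 (-3.93 ± 0.36, adjusted p = 3.46e-06). PR-1-LIKE (AT2G19990) changed by -3.37 ± 0.47, GH9B13 (AT4G02290), a glycosyl hydrolase of the endoglucanase family, by -2.94 ± 0.71, and TBL36 (AT3G54260) by -2.47 ± 0.42. GSTU20 (AT1G78370), a glutathione transferase, changed by -2.41 ± 0.33, CYP71B37 (AT3G26330), a cytochrome P450, by -2.19 ± 0.36 and TOPII (AT3G23890), DNA topoisomerase II, by -2.17 ± 0.26. EXPB3 (AT4G28250), a beta-expansin, changed by -2.31 ± 0.55, a call that was lost without replicate 2 of 0.5 h (adjusted p = 0.0814) or replicate 1 of 24 h (adjusted p = 0.0514). Among genes known here by locus code, AT1G74870 rose most, from 1.59 ± 0.0829 to 988 ± 15.2 (8.03 ± 0.82). Next came AT2G04050 (6.86 ± 0.63), AT5G28520 (6.82 ± 0.62) and AT2G41730 (6.67 ± 0.65), whose probe set is of a kind that can share probes with other transcripts. AT4G01390 (-4.58 ± 0.80), AT2G19970 (-3.64 ± 0.40) and AT5G52710 (-3.55 ± 0.48) fell.

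By group, the heat shock list held 5 measured members in roots, and at 24 h all 5 rose, both over all probe sets tested and adjusted over the list alone, with a median of 3.26 (camera's adjusted p = 2.74e-05, and adjusted p = 0.0761 with an estimated correlation). AT1G53540, a small heat shock protein, rose by 5.07 ± 0.66, AT5G48570, a prolyl isomerase of the FKBP family, by 3.26 ± 0.50 and AT2G29500 by 2.78 ± 0.52. In the wider chaperone list, which includes those 5, 11 of 15 members rose, with a median of 2.24 (camera's adjusted p = 8.03e-07, and adjusted p = 0.178 with an estimated correlation). HSA32, a protein of heat acclimation, rose by 2.24 ± 0.37. Of 18 further genes known to respond to abscisic acid, drought or salt, 10 rose and XERICO, a RING finger gene chosen after its value was seen, changed by -1.11 ± 0.15, not with 1 h as the reference (median 1.36, camera's adjusted p = 5.05e-06, and adjusted p = 0.0106 with an estimated correlation). 7 of 18 LEA and dehydrin genes rose, a count of 4 without replicate 1 of 24 h (median 0.61, camera's adjusted p = 0.00572, and adjusted p = 0.409 with an estimated correlation), among them AT3G02480 by 5.82 ± 0.67 and LEA4-5. SWEET sugar transporters moved up in 5 of 9 members, with SAG29, also of the senescence list, at 3.05 ± 0.51, SWEET2 at 2.95 ± 0.31 and SWEET8 at 2.88 ± 0.34 (median 1.97, camera's adjusted p = 1.03e-04, and adjusted p = 0.116 with an estimated correlation). Beta-glucosidase genes rose in 6 of 13 members, while BGLU44 changed by -1.59 ± 0.26 (median 0.85, camera's adjusted p = 0.00344, and adjusted p = 0.160 with an estimated correlation). Cytosolic ribosomal protein genes were lower as a group, with a median of -0.72 over 79 members, 8 of which passed (camera's adjusted p = 9.52e-16, and adjusted p = 0.344 with an estimated correlation). The mitotic kinases AUR1 (-1.41 ± 0.19) and AUR2 (-1.68 ± 0.25), the spindle checkpoint gene BUB3.1 (-1.62 ± 0.25) and PRL (-1.20 ± 0.19) were the 4 of 7 cell division genes that fell, PRL not with 1 h as the reference (list median -1.20, camera's adjusted p = 8.89e-04, and adjusted p = 0.178 with an estimated correlation).

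Photosynthesis genes, dim in roots, were higher at 24 h in 3 of 9 members over all probe sets and 3 adjusted over the list alone (median 0.75, camera's adjusted p = 9.23e-04, and adjusted p = 0.225 with an estimated correlation). Over all probe sets limma called 1 without replicate 1 of 0.5 h and no member without replicate 1 of 24 h. RCA, Rubisco activase, rose by 1.18 ± 0.19, and by 0.97, under 2-fold, without replicate 1 of 24 h; PSAE-1 and PSBW, of the photosystems, were the others, chosen after their values were seen. Plastid-encoded genes had a median of 0.46 over 69 members (camera's adjusted p = 1.39e-05, and adjusted p = 0.626 with an estimated correlation). In the same arrays the signal of 200 other shoot-specific probe sets, as a median percent of their level in shoots, was 3.11% and 2.68% at 24 h, against 1.73% and 2.21% at 0.5 h. The 200 lie outside the photosynthesis, plastid-encoded and chlorophyll lists, but only 9 of 45 fixed photosynthesis genes had a named probe set. Others may be among the 200, which therefore cannot tell shoot tissue from a change of photosynthesis genes.

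By 3 h many probe sets in roots had changed from 0.5 h, with stress-inducible genes higher as a group (camera's adjusted p = 0.0106 with an estimated correlation). GH3.1 (AT2G14960), of the family that conjugates auxin to amino acids, went from a signal of 15.5 ± 3.33 at 0.5 h to 292 ± 111 at 3 h and 622 ± 229.8 at 6 h (4.01 ± 0.57, adjusted p = 1.72e-04 at 3 h). scpl30 (AT4G15100), a serine carboxypeptidase-like protein, rose by 5.21 ± 0.35, BGLU27 by 4.48 ± 0.57 and COR15A (AT2G42540), a cold-regulated plastid protein, by 4.39 ± 0.79 to a signal of 118 ± 49.7. CYP71B37 (-2.45 ± 0.36), sks15 (AT4G37160, -2.42 ± 0.43) and MSRB5 (AT4G04830, a methionine sulfoxide reductase, -2.22 ± 0.28) fell. PR-1-LIKE changed by -2.12 ± 0.47, with an adjusted p of 0.0513 without replicate 1 of 3 h. Of genes with a locus code, AT1G22810 (6.39 ± 0.77), AT2G41730 (6.10 ± 0.65), AT5G43450 (5.85 ± 0.60) and AT3G53600 (5.67 ± 0.75) rose most, and AT3G49960 (-4.12 ± 0.72), AT4G26010 (-3.15 ± 0.37), AT5G04960 (-3.14 ± 0.59) and AT5G60520 (-3.13 ± 0.49) fell most. WRKY53 (2.42 ± 0.44), WRKY6 (2.46 ± 0.51) and STZ (2.12 ± 0.50), transcription factors of rapid stress and touch responses, rose, as did the calmodulin-like CML37 (3.89 ± 0.68) and CML38 (2.08 ± 0.53). Of these, WRKY6, STZ, CML37 and CML38 did not pass with 1 h as the reference, and CML38 did not without replicate 2 of 0.5 h (adjusted p = 0.0821).

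In the auxin list, 4 of 6 members rose at 3 h over all probe sets and 5 adjusted over the list alone, and 5 rose at 6 h (medians 1.77 and 1.72). For 3 h, camera's adjusted p = 3.36e-04, and adjusted p = 0.191 with an estimated correlation. IAA29, an auxin response repressor, rose by 2.08 ± 0.45 and LBD16, a regulator of lateral root formation, by 1.92 ± 0.33. 7 of 11 calmodulin-like and glutamate receptor genes rose at 3 h (camera's adjusted p = 0.00122, and adjusted p = 0.0866 with an estimated correlation). 13 of 18 stress-inducible genes rose (median 1.60, camera's adjusted p = 1.44e-07, and adjusted p = 0.0106 with an estimated correlation). Jasmonate genes rose in 3 of 7 members, OPCL1, of jasmonate synthesis (2.32 ± 0.50), ORA47, a transcription factor (3.18 ± 0.51), and JRG21 (3.19 ± 0.54), the first 2 of these not with 1 h as the reference, with a list median of 0.94 (camera's adjusted p = 0.00546, and adjusted p = 0.116 with an estimated correlation). Tubulin genes fell in 4 of 7 members at 3 h, a count of 2 without replicate 2 of 0.5 h and 2 without replicate 2 of 3 h, and in 4 at 6 h, where TUB1 changed by -2.86 ± 0.41 and TUB5 by -1.66 ± 0.21 (median -1.52, camera's adjusted p = 0.0231, and adjusted p = 0.475 with an estimated correlation). Ribosomal protein genes fell in 7 of 79 members at 3 h, a count of 17 without replicate 1 of 3 h and 3 without replicate 2 of 3 h, and in 42 at 6 h (medians -0.66 and -1.06). At 6 h camera's adjusted p = 2.74e-17, and adjusted p = 0.313 with an estimated correlation. Photosynthesis genes were lower in 3 of 9 members at 3 h, a count of 3 adjusted over the list alone, and 5 at 6 h (median -0.91 at 3 h, camera's adjusted p = 0.00580, and adjusted p = 0.289 with an estimated correlation). Over all probe sets limma called 5 without replicate 1 of 0.5 h and no member without replicate 2 of 0.5 h for 3 h, and 3 without replicate 2 of 0.5 h for 6 h. The 200 other shoot-specific probe sets were lower as well, at 1.43% and 1.39% of their level in shoots in the arrays of 3 h and 1.34% and 1.31% at 6 h, against 1.73% and 2.21% at 0.5 h.

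In roots, limma called 57 probe sets higher and 2 lower at 1 h, 1246 and 738 at 3 h, 1678 and 2000 at 6 h, 1039 and 1020 at 12 h, and 1219 and 991 at 24 h. The fit held 1 spread per probe set for all groups, so the median SE was 0.22 at 12 h as at the other times. Yet the log2 difference between the 2 root arrays of 12 h had an SD of 0.89, against 0.36 or less in the other root groups. The p-values of roots at 12 h therefore understate the spread of that group, and its counts may be too high. An F test over all times called 8988 probe sets, 59.1% of those tested. At 1 h the genes with a symbol that passed were scpl30, CCR2, GTR1 and CCT2, which were higher, and ECS1, which with 1 probe set without a symbol was lower (-1.19 ± 0.23); they were chosen after their values were seen. The count of 59 at 1 h rested on single arrays, as it was 17 and 15 without replicate 1 or 2 of 0.5 h, 15 and 8 without replicate 1 or 2 of 1 h, and 191 and 195 without replicate 1 or 2 of 12 h, whose spread enters the shared error. With each array centred on its median the split at 6 h became 1896 higher and 1535 lower. With no fold limit more were lower than higher. The counts were then 1877 and 3536 at 3 h, 1764 and 3196 at 12 h and 1953 and 3384 at 24 h. At 12 h the count of 2059 became 1826 without replicate 1 and 3412 without replicate 2 of that time. The near even split at 12 h was 1052 and 774 higher and lower without replicate 1 and 1561 and 1851 without replicate 2 of 12 h. It was 793 and 883 or 824 and 886 without replicate 1 or 2 of 0.5 h. Heat shock genes stood higher at 12 h in all 5 members of the list (median 2.46, camera's adjusted p = 1.05e-04, and adjusted p = 0.0761 with an estimated correlation), and the list passed without either 12 h array. AT2G29500 of this list was 1.23 (adjusted p = 0.0950) without replicate 1 of 12 h. The median over all probe sets in roots lay at -0.19 at 3 h, -0.21 at 6 h and -0.14 at 24 h relative to 0.5 h. The reference genes AT4G34270 (-0.62 ± 0.16) and GAPC2 (-0.67 ± 0.11) were lower at 6 h as well, by less than 2-fold. With 1 h as the reference, 1032 probe sets passed at 3 h in place of 1984, and the call of CML37 at 24 h was lost.

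**Figure D2:**
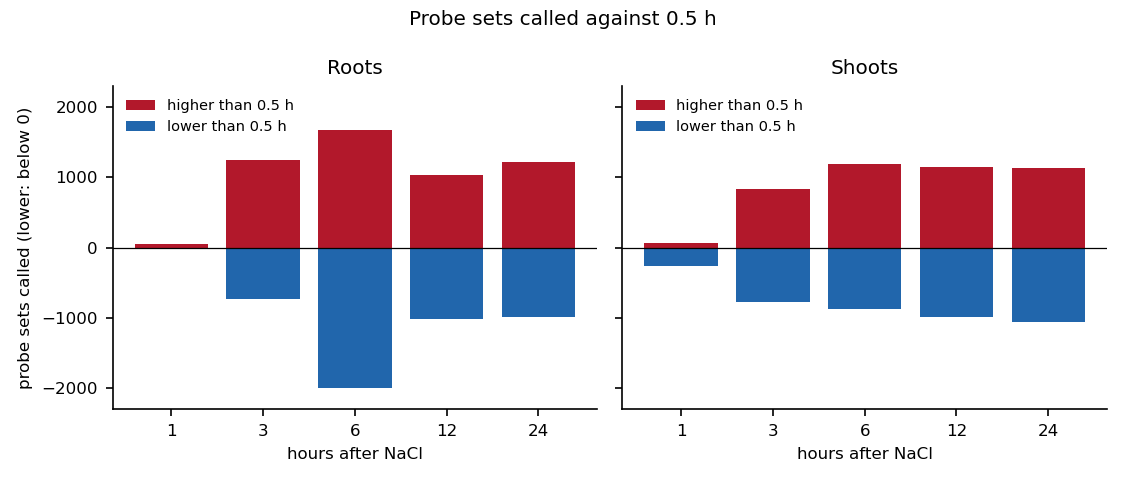
Number of probe sets called against 0.5 h in roots (left) and shoots (right) by hours after NaCl (horizontal axis, times spaced evenly), with those higher as bars above 0 and those lower as bars below 0 (vertical axis, number of probe sets). In roots the bars lie at 1219 higher and 991 lower at 24 h; in shoots they lie at 1136 and 1058 at 24 h.

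In shoots at 24 h, stress-inducible genes rose as a group (camera's adjusted p = 0.0104 with an estimated correlation). On the log2 scale used, which understates the change of dim genes, the expansin EXPA8 and the thionin THI2.2 fell furthest among genes with a symbol. LEA4-5 went from a signal of 8.02 ± 7.66 to 1227 ± 64.0 (7.15 ± 0.58, adjusted p = 2.02e-07). COR15A went from 36.3 ± 12.1 to 2599.9 ± 964 (6.06 ± 0.79) and LTI30 (AT3G50970), a dehydrin, from 17.9 ± 0.883 to 1198 ± 241 (5.89 ± 0.18, adjusted p = 4.73e-12). CHI (AT2G43570), a chitinase, rose by 4.78 ± 0.61, LEA18 (AT2G35300) by 4.16 ± 0.78, and APL3 (AT4G39210), a large subunit of the ADP-glucose pyrophosphorylase of starch synthesis, by 4.12 ± 0.35. PUB19 (AT1G60190), a U-box ubiquitin ligase, rose by 4.06 ± 0.39 and the sugar transporter SWEET4 (AT3G28007) by 4.05 ± 0.33. EXPA8 (AT2G40610), an expansin of growing walls, fell from 546 ± 71.0 to 0.816 ± 0.416 (-7.50 ± 0.51, adjusted p = 4.11e-08). THI2.2 (AT5G36910), a thionin, changed by -3.83 ± 0.23, and TBL45 (AT2G30010) by -3.42 ± 0.29. ALN (AT4G04955), allantoinase of purine breakdown, changed by -3.34 ± 0.27 and AKINBETA1 (AT5G21170), a beta subunit of the SnRK1 kinase, by -3.05 ± 0.22. ZCF37 (AT1G59590, -3.25 ± 0.73), CML38 (AT1G76650, -3.17 ± 0.53) and BZIP61 (AT3G58120, -3.11 ± 0.72) fell as well, calls that were lost with 1 h as the reference. AT3G02480 and AT3G17520, both in the LEA list, rose by 8.70 ± 0.67 and 8.23 ± 0.85, and AT1G16850 by 6.95 ± 0.58. AT5G62280 (-6.67 ± 0.70), AT3G62950 (-5.47 ± 0.59) and AT2G30600 (-5.18 ± 0.24) fell most among locus codes, and a second probe set of AT2G30600 changed by -4.11.

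By group, 13 of 18 LEA and dehydrin genes rose in shoots at 24 h, with a median of 3.26 (camera's adjusted p = 1.40e-11, and adjusted p = 0.111 with an estimated correlation). COR47, a dehydrin, rose by 3.11 ± 0.30 and COR15B by 3.26 ± 0.38. 12 of 18 stress-inducible genes rose, among them ALDH7B4, an aldehyde dehydrogenase, by 3.80 ± 0.27 and SAG29 by 3.96 ± 0.51. The ubiquitin ligase PUB22, chosen after its value was seen, changed by -2.64 ± 0.54 (median 2.21, camera's adjusted p = 3.48e-07, and adjusted p = 0.0104 with an estimated correlation). All 5 heat shock members rose, also adjusted over the list alone (median 2.47, camera's adjusted p = 0.00416, and adjusted p = 0.483 with an estimated correlation), and AT2G29500 had an adjusted p of 0.0517 without replicate 1 of 24 h. In the wider chaperone list 11 of 15 rose, with HSA32 at 3.69 ± 0.37 and AT2G20560 at 3.31 ± 0.35 (median 2.27, camera's adjusted p = 1.30e-06, and adjusted p = 0.338 with an estimated correlation). Ribosomal protein genes had a median of -0.52 (camera's adjusted p = 4.32e-11, and adjusted p = 0.738 with an estimated correlation). In the auxin list IAA29 (-2.45 ± 0.45) and WES1 (-1.27 ± 0.31, not with 1 h as the reference) fell, while the list as a whole did not pass (median 0.35, mean -0.29, camera's adjusted p = 0.825, and adjusted p = 0.980 with an estimated correlation). PORB, a protochlorophyllide reductase of chlorophyll synthesis, rose at 3 h (1.76 ± 0.32) and at 6 h (2.23 ± 0.32) and lay lower at 24 h (-1.84 ± 0.32). CHLM, of the same pathway, changed by -1.40 ± 0.16 at 24 h, and DFR, of anthocyanin synthesis, rose by 2.69 ± 0.63, with an adjusted p of 0.0596 without replicate 2 of 0.5 h.

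LTI30, COR15A and LEA4-5 of the LEA and dehydrin list were already higher in shoots at 3 h. LTI30 reached 989 ± 34.7 (5.63 ± 0.18), COR15A 2004 ± 616 (5.70 ± 0.79). LEA4-5 reached 519 ± 247 (5.82 ± 0.58) and PUB19 1243 ± 234 (5.49 ± 0.39), and AT3G02480 rose by 6.27 ± 0.67. BZIP61 (-4.27 ± 0.72) and TBL45 (-3.56 ± 0.29) fell, as did AT5G19120 (-4.83 ± 0.34). EXLA1 (AT3G45970, expansin-like, -2.73 ± 0.60), JKD (AT5G03150, a zinc finger protein, -2.52 ± 0.52), AT1G33055 (-4.54 ± 0.33) and AT2G20670 (-3.66 ± 0.73) passed against 0.5 h and not against 1 h. With that reference AT2G20670 had the opposite sign (2.11). 13 of 18 LEA and dehydrin genes rose (median 2.67, camera's adjusted p = 5.26e-11, and adjusted p = 0.119 with an estimated correlation). 10 of 18 stress-inducible genes rose (median 1.62, camera's adjusted p = 9.98e-07, and adjusted p = 0.0104 with an estimated correlation). Ribosomal protein genes fell in 8 of 79 members at 3 h, a count of 13 without replicate 1 of 3 h, and in 18 at 6 h (median -0.84 at 6 h, camera's adjusted p = 4.35e-25, and adjusted p = 0.475 with an estimated correlation). At 12 h photosynthesis genes were lower in 3 of 9 members, 3 adjusted over the list alone (median -0.73, camera's adjusted p = 0.00254, and adjusted p = 0.635 with an estimated correlation). Over all probe sets limma called 1 without replicate 1 of 12 h, and the list did not pass under quantile normalization (adjusted p = 0.309). GI, an evening-phased clock gene that marks time of day, rose in shoots by 1.92 ± 0.20 at 3 h and 2.85 ± 0.20 at 6 h. It was -0.72 ± 0.20 at 24 h, under 2-fold, and 0.023 ± 0.20 in roots at 6 h.

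In shoots, limma called 71 probe sets higher and 265 lower at 1 h, 836 and 772 at 3 h, 1188 and 871 at 6 h, 1146 and 988 at 12 h, and 1136 and 1058 at 24 h, and the F test over all times called 7521 (49.5%). Genes lower at 1 h included the autophagy gene ATG8E (-1.80 ± 0.20), and the wall enzyme EXGT-A3 (-1.74 ± 0.24); these were chosen after their values were seen. The count of 336 at 1 h was 150 without replicate 2 of 0.5 h and 165 without replicate 2 of 1 h. With each array centred on its median the split became 1036 higher and 1042 lower at 6 h and 1024 higher and 1101 lower at 12 h, and under quantile normalization it was 735 higher and 742 lower at 3 h.

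**Figure D3:**
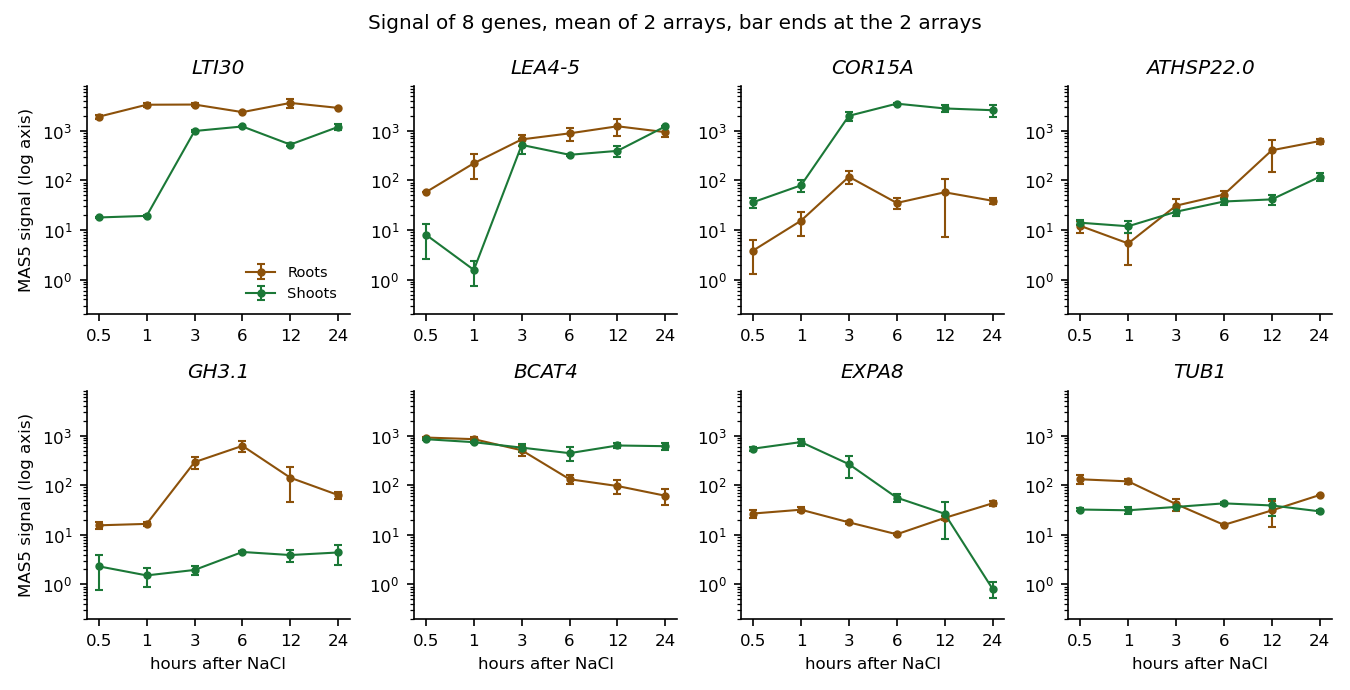
Signal on a log axis (vertical) by hours after NaCl (horizontal, times spaced evenly) for 8 genes in roots and shoots; points are means of 2 arrays and the ends of each bar are the values of these arrays. LTI30 stays between 1924 and 3646 in roots and goes from 17.9 to 1198 in shoots, while ATHSP22.0 reaches 621 in roots at 24 h.

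Whether the change differed between roots and shoots was tested as the interaction, the change in roots minus that in shoots. For these tests, higher or lower in roots relative to shoots refers to the change from 0.5 h, not to the level. As 0.5 h was itself after salt, a response before that time is not part of the change in either tissue. At 24 h the dehydrin LTI30 lay at 1924 ± 257 in roots at 0.5 h and 2896 ± 65.2 at 24 h, a change of 0.60 against 5.89 in shoots (interaction -5.29 ± 0.25, adjusted p = 6.06e-09). PUB19 (-3.90 ± 0.56) and COR15B (-3.51 ± 0.54) were also lower in roots relative to shoots. UGT73C1, a glycosyltransferase, differed by -3.97 (adjusted p = 0.00915), a call that was lost with no pseudocount; its root signals were 0.643 ± 0.310 and 0.772 ± 0.377. EXPA8, which fell in shoots, had a root change of 0.66 (interaction 8.16 ± 0.72, adjusted p = 2.65e-06), and NDB4 (6.19, adjusted p = 5.30e-04) and BGLU24 (4.68 ± 0.72) were higher in roots relative to shoots. ZCF37 changed by 2.77 in roots and -3.25 in shoots, an interaction of 6.02 ± 1.03 that was lost with 1 h as the reference. 11 of 18 LEA and dehydrin genes were lower in roots relative to shoots (median -2.34, camera's adjusted p = 4.92e-05, and adjusted p = 0.389 with an estimated correlation). Photosynthesis genes moved apart in 5 of 9 members over all probe sets and 7 adjusted over the list alone, and over all probe sets in 3 without replicate 1 of roots at 0.5 h, each higher in roots relative to shoots, with PSAN at 1.47 ± 0.32 (median 1.35, camera's adjusted p = 4.28e-05, and adjusted p = 0.376 with an estimated correlation); the shoot-specific signal in these root arrays is given above. At 3 h the transcription factor WRKY22 (AT4G01250) changed by 3.15 in roots and -1.64 in shoots (interaction 4.79 ± 0.69, adjusted p = 2.23e-04).

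Further interactions at 3 h were higher in roots for scpl30 (4.78 ± 0.50) and for XTH19 (AT4G30290), a xyloglucan endotransglucosylase/hydrolase of walls (4.35 ± 0.97). They were lower for LTI30 (-4.81 ± 0.25), COR15B (-4.66 ± 0.54), PUB19 (-4.22 ± 0.56) and HIS1-3, a linker histone of water stress (-3.32 ± 0.82). XTH18 differed by 4.75 ± 1.42 (adjusted p = 0.0215). This adjusted p was 0.120 without replicate 2 of shoots at 0.5 h, 0.0626 without replicate 1 of roots at 0.5 h, 0.0827 without replicate 1 of shoots at 3 h and 0.0649 without replicate 2 of roots at 3 h. The calls of XTH18, XTH19 and HIS1-3 were lost with 1 h as the reference. IAA29 (2.71 ± 0.64), GH3.1 (4.05 ± 0.81) and WES1 (1.88 ± 0.45) of the auxin list were higher in roots relative to shoots, 3 of 6 members over all probe sets and 4 adjusted over the list alone (median 1.63, camera's adjusted p = 0.0101, and adjusted p = 0.376 with an estimated correlation). Calmodulin-like and glutamate receptor genes were higher in roots relative to shoots by camera (median 1.25, camera's adjusted p = 0.00396, and adjusted p = 0.354 with an estimated correlation). Core histone genes were relatively higher in roots in 5 of 8 members and in 3 without replicate 1 of roots at 0.5 h, AT3G09480 by 2.86 ± 0.40 among them (median 1.11, camera's adjusted p = 1.58e-04, and adjusted p = 0.354 with an estimated correlation). By time, 188 probe sets were higher and 31 lower in roots relative to shoots at 1 h, 1351 and 1468 at 3 h, 1726 and 2814 at 6 h, 1318 and 1794 at 12 h, and 1368 and 1276 at 24 h. At 12 h the shared spread of the fit understates that of the 2 root arrays, so the counts there may be too high. With each array centred on its median the split became 1440 higher and 1247 lower at 3 h, where quantile normalization gave 1491 and 1271, 2096 and 1993 at 6 h and 1559 and 1320 at 12 h. At 24 h the majority turned with no fold limit (1644 and 2340) and without single arrays. The split was 1144 and 1194 or 1019 and 1025 without replicate 1 or 2 of shoots at 0.5 h, 1057 and 1095 without replicate 1 of roots at 0.5 h, 1059 and 1097 without replicate 1 of shoots at 24 h and 1153 and 1242 without replicate 2 of roots at 24 h. The total of 3112 at 12 h was 2684 without root replicate 1 and 4794 without root replicate 2 of that time. At 1 h the total of 219 was 76 without replicate 2 of shoots at 0.5 h, 117 and 79 without replicate 1 or 2 of roots at 0.5 h, 104 without replicate 2 of shoots at 1 h, 104 and 103 without replicate 1 or 2 of roots at 1 h, and 506 and 508 without replicate 1 or 2 of roots at 12 h.

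**Figure D4:**
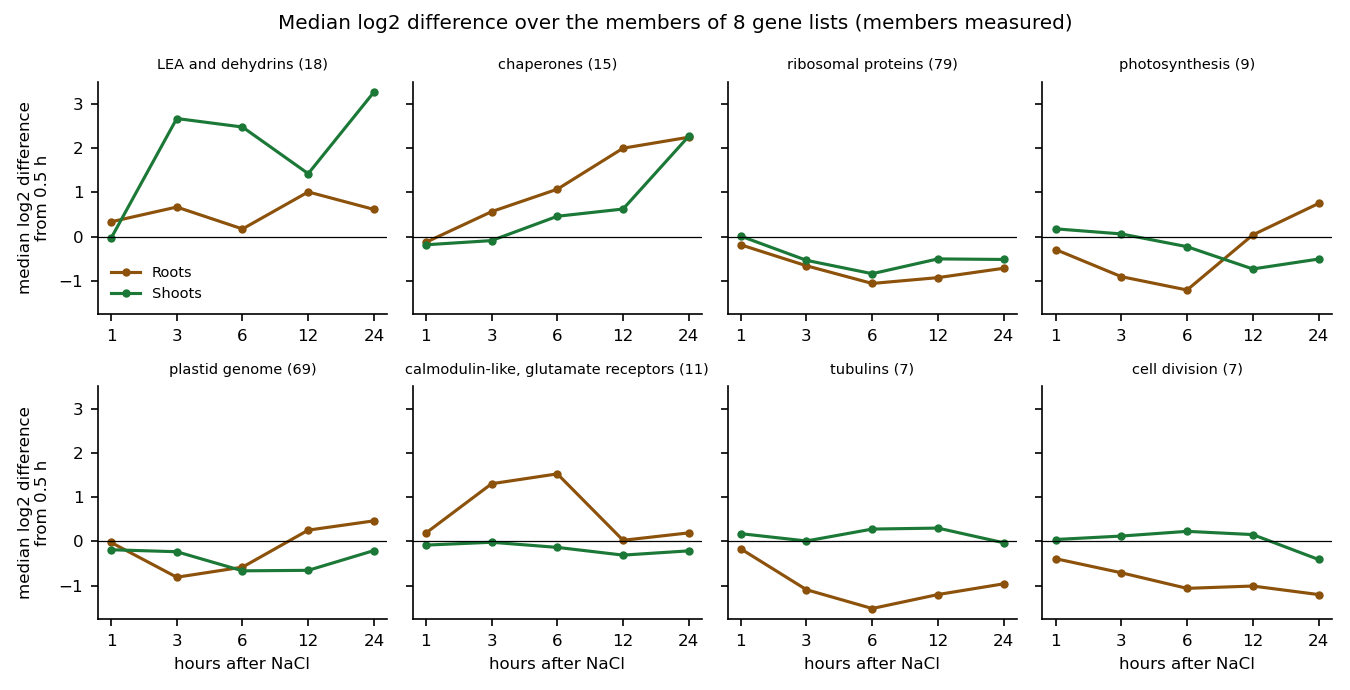
Median log2 difference from 0.5 h (vertical axis) over the members of 8 gene lists by hours after NaCl (horizontal axis, times spaced evenly), with a line per tissue and the number of members in brackets. LEA and dehydrin genes stand at 3.26 in shoots and 0.61 in roots at 24 h, and ribosomal protein genes lie below 0 in both tissues from 3 h on.

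Roots and shoots shared part of their calls. At 24 h 314 probe sets were higher in both tissues, where independent lists of these sizes would share 91.1, and 196 were lower in both, against 69.0. Opposite calls at 24 h numbered 83 for higher in roots and lower in shoots, against 84.9, and 20 for the reverse, against 74.1. At 3 h 175 were higher in both, against 68.5, and 71 lower in both, against 37.5. Opposite calls at 3 h numbered 107 for higher in roots and lower in shoots, more than the 63.3 of independent lists, and 13 for the reverse, against 40.6. Across probe sets, the log2 differences of roots and shoots correlated with Pearson r = 0.12 and Spearman rho = 0.12 at 3 h and 0.27 and 0.25 at 24 h, and probe sets are not independent replicates. The tissues have their own 0.5 h arrays, so no control is shared. Both sets of calls do share 1 spread per probe set, so probe sets of small spread are called more readily in both tissues. Part of the sharing above independent lists may come from this. It would raise opposite calls as well, of which 107 at 3 h lay above independent lists and the others given here did not. RD29A, RD29B, RAB18, SOS1, CCA1, TOC1 and RBCS1A were not analysed here, since no probe set carried their name in the gene table used.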

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

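Some tests were chosen only after the result was seen. They were those of another root time label and of a weaker response in replicate 2 at 12 h. The share of gaps that shoot tissue could close and the tests of explanations for the LEA and dehydrin genes were also chosen then. The results below stand here because the change differed between roots and shoots by the interaction test. It called 219 probe sets at 1 h, 2819 at 3 h, 4540 at 6 h, 3112 at 12 h and 2644 at 24 h; the values without single arrays at 1 h and 12 h stand with these counts above. List medians of the interaction, as log2 of roots minus shoots, were at 3 h auxin 1.63, photosynthesis -0.91, plastid-encoded -0.57, LEA and dehydrin -1.42, jasmonate 2.16, calmodulin-like and glutamate receptor 1.25, histone 1.11 and cell division -0.75. At 24 h they were photosynthesis 1.35, plastid-encoded 0.67, LEA and dehydrin -2.34, endoplasmic reticulum body 1.59, further photosynthesis 1.02 and calmodulin-like and glutamate receptor 0.74. With an estimated correlation no list test of the interaction passed by camera, 1 of the fixed and 12 of the added lists' tests having an unadjusted p under 0.05. The shoot-specific signal in roots, given above, was lower at 3 h and higher at 24 h than at 0.5 h, as were photosynthesis and plastid-encoded genes there. At 3 h the photosynthesis list had an adjusted p of 0.0565 without replicate 1 of shoots at 0.5 h and 0.0702 without replicate 2 of roots at 0.5 h. The cell division list had 0.0628 without replicate 2 of shoots at 0.5 h and 0.0616 without replicate 2 of roots at 0.5 h.

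Named genes with a higher change in roots at 24 h, as log2 interaction, were NDB4 6.19, ATHSP22.0 2.61, BGLU24 4.68, COR27 4.28, BGLU27 3.71, JRG21 3.79, CML37 3.85, AT1G74870 8.46, AT2G04050 5.63, AT5G28520 6.77, AT2G41730 6.89, EXPA8 8.16, THI2.2 3.38, TBL45 2.83, ALN 2.05, ZCF37 6.02, CML38 2.37, BZIP61 2.86, AKINBETA1 3.07, AT5G62280 5.83, AT3G62950 5.57, AT2G30600 5.03 and AT4G16680 6.89. Those with a lower change in roots at 24 h were LEA4-5 -3.21, BCAT4 -3.45, PR-1-LIKE -3.41, GSTU20 -2.07, CYP71B37 -1.97, AT2G19970 -3.24, AT5G52710 -4.01, COR15A -3.17, LTI30 -5.29, CHI -2.74, APL3 -1.46, PUB19 -3.90, SWEET4 -2.08, AT3G02480 -2.88, AT1G16850 -5.25, UGT73C1 -3.97, COR15B -3.51, AT1G57590 -5.32 and AT3G57010 -4.96. These calls were repeated without each of the 8 arrays they rest on, and some were lost. For ATHSP22.0 the adjusted p was 0.0508 to 0.102 without any 1 of the 8 arrays but replicate 1 of shoots at 24 h and replicate 1 of roots at 0.5 h. For LEA4-5 it was 0.0525 without replicate 1 of shoots at 0.5 h. For CYP71B37 it was 0.0546 without replicate 2 of roots at 0.5 h and 0.0542 without replicate 1 of roots at 24 h. For COR15A the adjusted p was 0.0650 to 0.166 without any 1 of the 8 arrays but replicate 1 of roots at 0.5 h. For CHI the adjusted p was 0.0546 to 0.133 without any 1 of the 8 arrays but replicate 2 of shoots at 0.5 h and replicate 2 of shoots at 24 h. For APL3 the adjusted p was 0.0649 to 0.133 without any 1 of the 8 arrays but replicate 1 of shoots at 0.5 h and replicate 1 of roots at 0.5 h. For CML38 the adjusted p was 0.0503 to 0.117 without any 1 of the 8 arrays but replicate 1 of shoots at 0.5 h, replicate 1 of shoots at 24 h and replicate 1 of roots at 0.5 h. For BZIP61 the adjusted p was 0.0834 to 0.128 without any 1 of the 8 arrays. For AT3G02480 the adjusted p was 0.0619 to 0.140 without any 1 of the 8 arrays but replicate 2 of shoots at 0.5 h. Calls at 24 h were also lost with no pseudocount for ATHSP22.0, BGLU27, CML37, AT2G19970, COR15A, APL3, BZIP61, AT3G02480 and UGT73C1, with 1 h as the reference for CML37, CYP71B37, APL3, SWEET4, ZCF37, BZIP61 and AT3G62950, with quantile normalization for COR15A, CHI, APL3, BZIP61 and AT3G02480, with median centring for COR15A, with no filter for COR15A, APL3 and BZIP61, with no trend for COR15A and BZIP61 and with the 30th percentile pseudocount for CHI and CML38. CML38 turned to -0.55 with that 1 h reference.

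At 3 h, higher changes in roots were scpl30 4.78, BGLU27 3.42, GH3.1 4.05, AT1G22810 5.93, AT2G41730 6.25, AT5G43450 5.71, AT3G53600 5.34, BZIP61 3.79, TBL45 3.26, EXLA1 2.35, JKD 2.55, AT5G19120 5.02, AT1G33055 5.82, AT2G20670 3.78, WRKY22 4.79, XTH18 4.75, XTH19 4.35 and AT2G25735 6.25. Lower changes in roots at 3 h were CYP71B37 -2.97, sks15 -3.25, MSRB5 -2.21, PR-1-LIKE -2.05, AT3G49960 -4.09, AT4G26010 -3.68, AT5G04960 -3.87, AT5G60520 -3.20, LEA4-5 -2.39, LTI30 -4.81, PUB19 -4.22, COR15B -4.66, HIS1-3 -3.32, AT1G20030 -5.21 and AT2G21820 -4.49. Some of these were lost without single arrays as well. For PR-1-LIKE the adjusted p was 0.0658 to 0.150 without any 1 of the 8 arrays but replicate 1 of shoots at 0.5 h, replicate 2 of shoots at 3 h and replicate 2 of roots at 3 h. For LEA4-5 the adjusted p was 0.0858 to 0.190 without any 1 of the 8 arrays but replicate 2 of shoots at 0.5 h, replicate 2 of shoots at 3 h and replicate 1 of roots at 3 h. For EXLA1 the adjusted p was 0.0743 to 0.166 without any 1 of the 8 arrays but replicate 1 of shoots at 3 h. For JKD it was 0.0607 without replicate 1 of shoots at 0.5 h, 0.0629 without replicate 1 of roots at 0.5 h and 0.0557 without replicate 2 of roots at 3 h. For XTH18 the adjusted p was 0.0626 to 0.120 without any 1 of the 8 arrays but replicate 1 of shoots at 0.5 h, replicate 2 of shoots at 3 h, replicate 2 of roots at 0.5 h and replicate 1 of roots at 3 h. Calls at 3 h were also lost with no pseudocount for BGLU27 and PR-1-LIKE, with 1 h as the reference for PR-1-LIKE, AT3G53600, AT3G49960, BZIP61, EXLA1, JKD, AT1G33055, XTH18, XTH19, HIS1-3 and AT2G25735, with the 30th percentile pseudocount for LEA4-5 and EXLA1, with quantile normalization for LEA4-5, with no filter for LEA4-5 and EXLA1, with no trend for EXLA1 and with a replicate block for EXLA1. With 1 h as the reference AT2G20670 turned to -1.50.

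The 2 root arrays of 12 h lay far apart. The highest correlation of either with a root array of another time was 0.954, below the lowest of the other root pairs, 0.977, which argues against an array of another time under this label. Of 2902 probe sets at least 2-fold apart, 36.4% had replicate 2 between replicate 1 and the 0.5 h mean. This cannot decide whether replicate 2 responded less, since 0.5 h was itself after salt and at another time of day. A weaker response stays open. Of the 2902, 3.07% had a gap that adding shoot tissue could close, at the 90th percentile of its markers. This argues against shoot tissue as the whole cause. A small share of shoot tissue stays open: shoot-specific probe sets reached 2.34% of their shoot level in replicate 2 and 1.52% in replicate 1, against at most 2.21% in the 8 root arrays of earlier times and 3.11% at 24 h, where shoot tissue is itself open. No other biological explanation was tested, and a difference in handling or sampling of these samples may remain.

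Photosynthesis genes moved apart between roots and shoots at 24 h by camera (adjusted p = 0.376 with an estimated correlation). The median interaction stayed at 1.25 or more under quantile normalization and median centring, against 1.35 with the deposited scaling, which argues against scaling. Shoot tissue in the root samples of 24 h may account for part of the rise in roots and stays open. The 200 other shoot-specific probe sets had a median change of 0.41 in roots, between no change and the 0.75 of the list. This cannot decide the question, since the 200 may hold photosynthesis genes without a name in the gene table. A difference between the tissues in response is untested and open as well.

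At 24 h LEA and dehydrin genes had a lower change in roots than in shoots by camera (adjusted p = 0.389 with an estimated correlation). This does not describe their level, as LTI30 read 2896 in roots and 1198 in shoots at 24 h. The 0.5 h arrays were themselves after salt, so without untreated plants a rise in roots before 0.5 h can be neither seen nor excluded. A high level in roots at 0.5 h may leave less room to rise. Of the 11 members called lower, 6 (54.5%) had a root signal at 0.5 h at least 2-fold that of shoots. That is too few to explain all and too many to exclude it. Among the 6, LEA4-5 (58.0) and AT3G02480 (24.6) were not high in roots at 0.5 h and rose there to 939 and 1525 at 24 h. COR15A, COR15B and AT2G42560, 3 of 11 (27.3%), read at least 2-fold higher in both arrays of another group than in roots at 24 h. HVA22C, just short of that, had a root signal of 77.7 against 1640.3 at the top 1% of values. AT3G02480, also just short, read 3438 or more in both shoot arrays of 24 h and 1757 or less in both root arrays. These values argue against a limit of the measured range in these members. Such a limit stays open for COR47, LTI30, DI21 and AT2G23120. These 4 of 11 (36.4%) had a root signal at 24 h above that of shoots or in the top 1%. It also stays open for LEA4-5 and AT2G44060, which met neither test. In roots DI21 (922 to 738), AT2G23120 (2050 to 1953) and AT2G44060 (1136 to 992) read lower at 24 h than at 0.5 h. A limit alone would not give such a fall, but each was under 2-fold. A difference between the tissues in response stays open, untested.

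For the tissue comparison, 1 of 100 splits of the 24 arrays into 12 and 12, the real one, called as many probe sets in a fit of 2 groups. The real split called 6181 and the highest other 2948. Every other split mixes roots with shoots, whose difference then enters its spread. The test could therefore hardly come out otherwise, and it excludes nothing.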

How the results depend on the processing

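Fits without the root arrays of 12 h, the tests of genes known by locus code and all tests of the added lists were chosen after the data or the gene names were seen; the other alternatives were planned. Of 576 called values of named genes, 548 kept direction and call under quantile normalization, 559 under median centring, 554 with no pseudocount, 513 with the 30th percentile, 562 with no filter, 570 with no trend, 507 at an adjusted p under 0.01 and 575 with replicate number as a block. With 1 array left out, the other array of its group being assumed to vary like the other groups, 2463 of 2868 did, and with 1 h as the reference 392 of 568. Signs turned only under that reference, in which the 1 h arrays replace 0.5 h: AT2G20670 (shoots 3 h) 2.11, WRKY53 (shoots 12 h) 0.084, WRKY53 (shoots 24 h) 0.16, CML38 (interaction 3 h) -0.092, CML38 (interaction 24 h) -0.55, WRKY6 (interaction 3 h) -0.63, WRKY6 (interaction 24 h) -0.33, AT5G38710 (roots 6 h) -0.32, AT5G38710 (roots 12 h) -0.55, AT5G38710 (interaction 24 h) -0.74, ATG8E (shoots 3 h) 0.68, ATG8E (shoots 6 h) 0.20, CYP71B26 (interaction 24 h) 0.15, CYP71B29 (shoots 3 h) 0.20, EXGT-A3 (interaction 24 h) -0.43, NAI1 (shoots 3 h) 0.23, NAI1 (interaction 3 h) -0.33, NAI1 (interaction 24 h) -0.50, ORA47 (roots 24 h) -0.35 and ORA47 (interaction 24 h) -0.13. By replicate number, residuals of 66 pairs of groups correlated from -0.257 to 0.229 (median -0.0049), and 5 pairs lay over 0.1. A link by replicate number in some groups is therefore not excluded.

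With no fold limit, which by construction calls more, counts in roots were 5413 at 3 h, 7652 at 6 h, 4960 at 12 h and 5337 at 24 h; in shoots 544 at 1 h, 3692 at 3 h, 4767 at 6 h, 4728 at 12 h and 4813 at 24 h; 3984 for the interaction at 24 h and 12939 between tissues. The majority then turned, to 1877 and 3536 higher and lower in roots at 3 h, 1764 and 3196 at 12 h, 1953 and 3384 at 24 h, 1837 and 1855 in shoots at 3 h and 1644 and 2340 for the interaction at 24 h. It also turned with the 30th percentile pseudocount in roots at 6 h (1481 and 1447) and for the interaction at 3 h (1358 and 1204), and in roots at 12 h with no pseudocount (988 and 1021), no filter (1143 and 1194), an adjusted p under 0.01 (743 and 834) and each tissue alone (890 and 952). With an adjusted p under 0.01, counts were 25 in roots and 197 in shoots at 1 h, and for the interaction 77 at 1 h, 1725 at 3 h, 2036 at 12 h and 1620 at 24 h. With 1 h as the reference they were 1032 in roots at 3 h, and 1277 at 3 h and 2026 at 12 h for the interaction. Roots at 1 h gave 20 with each tissue alone, the cause of which was not tested. Without both root arrays of 12 h, whose spread enters the shared error, roots at 1 h gave 192 and the interaction at 1 h 510. With single arrays left out, counts ranged from 8 to 195 in roots at 1 h, 1676 to 3412 in roots at 12 h, 150 to 452 in shoots at 1 h, 76 to 508 for the interaction at 1 h and 2415 to 4794 at 12 h. Spearman's rho between the tissues at 24 h was 0.194 with no filter.

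Of 134 passing list tests by camera, 8 passed with an estimated correlation, 106 by fry in one direction, 128 under quantile normalization and 134 with the block. For the fixed lists, camera with an estimated correlation passed 0 tests in roots (2 at an unadjusted p under 0.05), 0 in shoots (1) and 0 in the interaction (1), where fry passed 9, 3 and 7. For the added lists it passed 4 in roots, 4 in shoots and 0 in the interaction (12 unadjusted, fry 41). By fry's mixed test, the added lists passed in 79 of 115 tests in roots, 79 in shoots and 76 in the interaction, and the fixed lists in 7 of 15 in roots, 1 in shoots and 1 in the interaction. Fry in one direction passed 43 of 115 tests of the added lists in shoots, and quantile normalization 1 of 15 tests of the fixed lists there; the cause was not tested. Signals near the background limit what low genes can show, as the pseudocount damps their changes.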

Other observations

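The lists below were written after the gene names were seen and before any difference was computed, and no test here was chosen after its result was seen. In the comparisons in which a list passed, its median kept its sign under quantile normalization and median centring. Endoplasmic reticulum body genes, of a store of beta-glucosidases, fell in shoots at 24 h in 5 of 7 members, a count of 2 without replicate 1 of 0.5 h and 3 without replicate 1 of 24 h (median -1.12, camera's adjusted p = 0.00806, and adjusted p = 0.642 with an estimated correlation), with JAL34, a jacalin-related lectin, at -1.93 ± 0.28. Vacuolar genes were higher as a group in shoots at 24 h, 1 of 6 members passing (median 0.73, camera's adjusted p = 0.00298, and adjusted p = 0.338 with an estimated correlation). ATG8E, of the autophagosome, rose in roots at 24 h (1.67 ± 0.20) and fell in shoots (-2.70 ± 0.20), with an interaction of 4.37 ± 0.28, adjusted p = 1.30e-07. The fall in shoots did not pass with 1 h as the reference. The autophagy list passed in roots at 24 h with 2 of 10 members higher (median 0.13, camera's adjusted p = 0.0185, and adjusted p = 0.407 with an estimated correlation). SWEET2, a sugar transporter, rose in roots (2.95 ± 0.31) and fell in shoots (-1.21 ± 0.31), with an interaction of 4.16 ± 0.43, adjusted p = 1.47e-05. In shoots it was -0.95 without replicate 2 of 0.5 h and -0.99 without replicate 1 of 24 h, under 2-fold, and it did not pass with 1 h as the reference. Histone genes were lower in shoots at 24 h in 2 of 8 members (median -0.83, camera's adjusted p = 0.00271, and adjusted p = 0.475 with an estimated correlation). Plastid-encoded genes were lower as a group in roots at 3 h (median -0.81, camera's adjusted p = 7.39e-07, and adjusted p = 0.582 with an estimated correlation) and in shoots at 6 h (median -0.67, camera's adjusted p = 4.53e-08, and adjusted p = 0.781 with an estimated correlation). In the same root arrays 200 other shoot-specific probe sets lay at 1.43% and 1.39% of their level in shoots at 3 h, against 1.73% and 2.21% at 0.5 h.

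UDP-glycosyltransferase genes rose in roots at 24 h in 7 of 36 members, a count of 4 without replicate 1 of 0.5 h (median 0.35, camera's adjusted p = 0.00559, and adjusted p = 0.205 with an estimated correlation). CYP71B genes rose in 3 of 11 members, a count of 1 without replicate 1 of 0.5 h, while 1 was lower (median 0.79, camera's adjusted p = 0.0225, and adjusted p = 0.264 with an estimated correlation). Further photosynthesis genes rose in 4 of 17, a count of 1 without replicate 1 of 0.5 h and 1 without replicate 1 of 24 h (median 0.47, camera's adjusted p = 0.00558, and adjusted p = 0.313 with an estimated correlation). In the same arrays the shoot-specific probe sets stood at 3.11% and 2.68%, against 1.73% and 2.21% at 0.5 h. Mitochondrially encoded genes were lower as a group in shoots at 6 h (median -0.89, camera's adjusted p = 0.0353, and adjusted p = 0.783 with an estimated correlation), and this was lost without replicate 2 of 0.5 h (camera's adjusted p = 0.0568) or replicate 1 of 6 h (0.0937). The lists of endoplasmic reticulum stress, glutathione transferases, tetraspanins and wall loosening passed at no time. The smallest camera adjusted p was 0.460 in roots, 0.451 in shoots, 0.611 in the interaction for endoplasmic reticulum stress, 0.434 in roots, 0.133 in shoots, 0.144 in the interaction for glutathione transferases, 0.327 in roots, 0.299 in shoots, 0.347 in the interaction for tetraspanins and 0.122 in roots, 0.248 in shoots, 0.119 in the interaction for wall loosening. Single members moved all the same: BZIP60, a transcription factor of the unfolded protein response, rose in roots at 24 h by 2.46 ± 0.43.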
